A study of Homo sapiens with 9 samples.

How the data were processed

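Poly(A) RNA was sequenced from human alveolar epithelial type 2 cells made from induced pluripotent stem cells (iAEC2s). All cells came from BU3, an induced pluripotent stem cell line in which both copies of ABCA3 carry GFP fused to the C-terminus of the protein. The 3 groups were wild-type ABCA3 (WT), a clone with E690K on both alleles and a clone with W308R on both alleles, with 3 libraries each. Per the labels, the 3 replicates of a line were separated at day 0 of differentiation, the cells were sorted on day 15 (CD47 high, CD26 low) and on day 30 (CPM), and live GFP-positive cells were collected by a further sort on day 43. Libraries were made with the TruSeq RNA kit, version 2, per the labels' protocols, a kit that does not mark strand. Reads from a gene and from an overlapping gene on the opposite strand therefore cannot be told apart.

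The authors deposited a table of raw read counts, whole numbers per gene with 1 column per library and no normalization. STAR, edgeR, limma and the genome build GRCh38 are named in the submitters' processing notes, without versions or roles. The counter, the annotation release and the gene filter are not given in the sources used here. The table held 17233 genes, including a line for EGFP beside the Ensembl genes. The third-highest value of a gene over the 9 libraries was never below 0.252 CPM (counts scaled to library size), equal to 10 counts at the median depth, so the table holds no gene below that level. No sample column was left unused, and no gene had 0 counts in all 9 libraries. Gene coordinates were taken from GENCODE release 29 on GRCh38, in which 17207 of the 17233 identifiers were found; 11 symbols belonged to more than 1 identifier.

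Total counts lay between 35917462 and 46201707 per library. In simulated data with 200 genes changed in E690K, edgeR recovered 49.3% of 1.5-fold, 83.6% of 2-fold and 100% of 4-fold changes against WT among 17233 genes, with 15 false calls. With 200 genes changed in W308R, it recovered 52.2%, 85.1% and 98.5% of such changes against WT, with 10 false calls. Intervals and floors quoted for counts cover counting error only, because the reads carry no molecular identifiers.

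Library sizes were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3), and CPM values and their SDs were computed on that scale. Genes were kept by the default filter of edgeR, which kept all 17233. A single quasi-likelihood model with robust dispersion and a coefficient per genotype was fitted to all 9 libraries, so that the 3 comparisons share an estimate of the spread. No block was used. Genes were called at a Benjamini-Hochberg (BH) adjusted p under 0.05. The standard error (SE) of a log2 fold change was its size over the square root of the F statistic. A fold against a group with 0 counts in every library was given as a bound against a floor of 3 counts per library.

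Before the data were examined, 38 gene lists with 738 entries were written: pathways and programs of type 2 cells, stress, signaling and growth, and markers of other cell types that the culture could hold. Of these entries, 663 were measured, and the 35 lists with at least 5 measured members were tested. The test was camera (limma 3.58.1) on voom log2 CPM, 2-sided, with a preset inter-gene correlation of 0.01 and BH adjustment over the lists. Camera compares a list with the other genes; fry, an alternative, tests whether the genes of a list move on balance in 1 direction and makes no such comparison. Counts of called members were also made with the adjustment over the list alone.

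The genes to be named were set by a rule written before the data were examined. It took ABCA3, SFTPC, SFTPB, SFTPA1, NAPSA, LAMP3, SLC34A2 and NKX2-1 in every comparison. It then took the 8 highest and 8 lowest fold changes in each mutant against WT and the 5 highest and 5 lowest between the mutants. These had to be called, to have a mean of at least 5 CPM over the 6 libraries, to separate the groups without overlap and to have a symbol of their own. The rule also took the 3 members with the smallest p of each list described, and the 6 genes with the largest shared change in both mutants. Genes that report sex were not named, and not every gene the rule took is described. EGFP was added after its values were seen.

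Genotype and clone cannot be told apart, since each genotype is a single clone. Nothing but the statement that replicates were separated at day 0 speaks to their independence, so p-values measure the spread between these libraries. Both mutants share the WT libraries, so correlations and overlaps between them were set beside values from 20 simulations of unchanged groups. The alternatives tried were DESeq2 1.42.0, limma voom, other scaling factors, other filters, the replicate number as a block, a fit without mitochondrially encoded genes, a fit of only the 6 libraries compared, each library left out, and for lists an estimated correlation and fry. Offsets for GC content and transcript length, the estimated correlation and the counts of list members without E690K library 3, and a term for the sign of the GC trend of a library were added after the data were seen. The libraries differed by more than sampling noise in every pair, so none was merged.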

Results

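ABCA3 is the lipid transporter of the lamellar body, the organelle in which alveolar type 2 cells store surfactant. The series asked how iAEC2s that carry a substitution in this protein differ in their transcriptome from cells with the wild-type protein. RNA was counted in 9 libraries of sorted, live, GFP-positive cells on day 43 of differentiation: 3 of WT, 3 of E690K and 3 of W308R. Since GFP sits on ABCA3 itself, the sort kept cells that made the fusion protein. Total counts ranged from 35917462 to 46201707 per library. Levels are given as TMM-normalised CPM, mean ± SD of 3 libraries, and changes as log2 fold changes with their SE.

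Libraries of a genotype lay closer to each other than to the other genotypes. Pearson correlations of log2 CPM across genes were 0.9865 to 0.989 among WT libraries, 0.9776 to 0.9926 among E690K, 0.9854 to 0.9897 among W308R, and 0.9559 to 0.9765 between genotypes. The first principal component held 34.7% of the variance and ran from WT to E690K, and the next held 25.9% and set W308R apart. The third component, with 12.5%, split the libraries within the mutants. E690K library 3 lay at 44.7 on it, E690K libraries 1 and 2 at -27.5 and -32.4, W308R library 1 at -17.0, W308R libraries 2 and 3 at 11.2 and 14.5, and the WT libraries between 1.54 and 2.63. Mitochondrially encoded transcripts made up 1.28% of the counts of E690K library 3, against 7.88% and 7.78% in the other E690K libraries, 6.89% to 7.72% in WT and 5.49% to 6.58% in W308R. The labels give no batch. In the joint test, 5906 of 17233 genes differed among the 3 genotypes (edgeR, BH-adjusted p under 0.05).

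**Figure D1:**
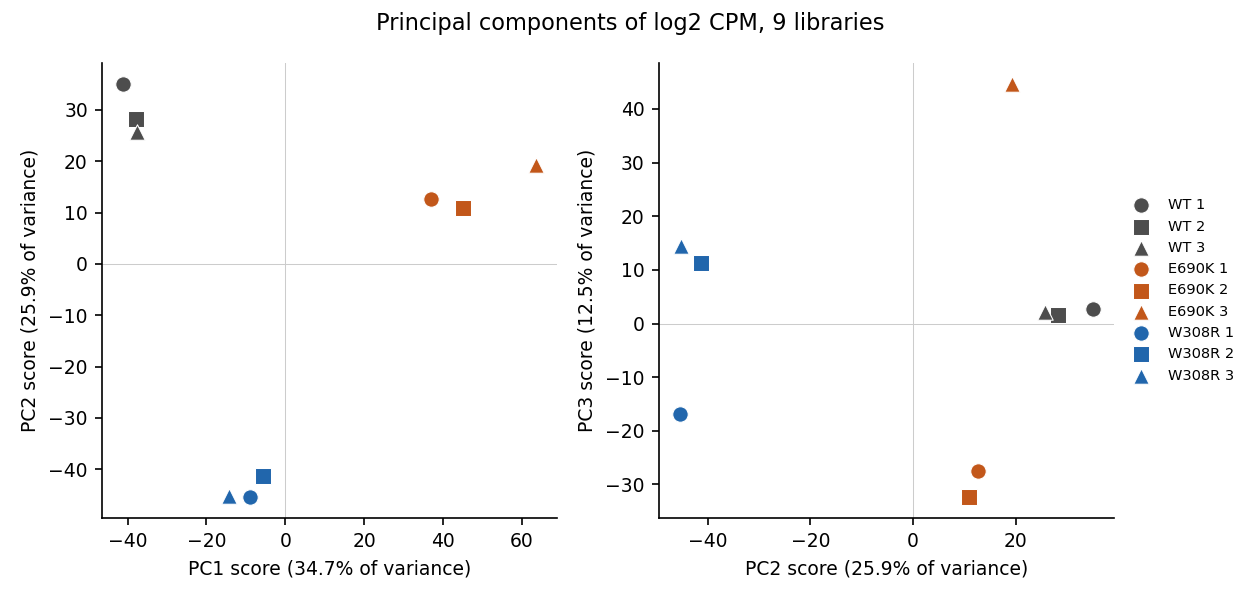
Each point is a library, placed by its scores on principal components of log2 CPM, with the percent of variance on each axis and the genotype as colour. The genotypes separate on the first pair of components (34.7% and 25.9%), and E690K library 3 lies apart from the other E690K libraries on the third (44.7 against -27.5 and -32.4).

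E690K against WT. The E690K cells had lower transcripts of the surfactant and lamellar body machinery and of lipid synthesis, and higher transcripts of neuroendocrine, lung progenitor and cell cycle genes. These are calls at a preset correlation (camera); 0 of 35 lists were called with an estimated correlation (14 at an unadjusted p under 0.05; 21 with fry). ABCA3 itself (chr16 2275881 to 2340746, GRCh38) fell from 1530 ± 86.6 to 815.5 ± 53.4 CPM, a log2 change of -0.91 ± 0.0998 (SE). SFTPB (chr2 85657314 to 85668741), which encodes the surfactant protein B precursor, fell from 19980 ± 864 to 7547 ± 830 CPM. SFTPC (chr8 22156913 to 22164479), the surfactant protein C precursor and the defining transcript of this cell type, fell from 4693 ± 47.9 to 1315 ± 520 CPM. Among the largest changes, PCSK1, a prohormone convertase, was 97.2-fold higher, and TTR, which encodes the carrier transthyretin, was 10.5-fold lower. PCSK1 lay at 0.114, 0.112 and 0.091 CPM in WT libraries 1, 2 and 3, below the 0.252 CPM of 10 counts. The size of its fold is therefore uncertain.

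Of 17233 genes, 1937 rose and 1854 fell in E690K (edgeR, BH-adjusted p under 0.05), and 565 and 503 of them by more than 2-fold. For 42.0% of genes the groups did not overlap, where chance gives 10%. The count was 2405, 2278 and 2295 without WT library 1, 2 or 3. It was 5424 without E690K library 3, and 3560 of the 3791 genes were called in the same direction in that fit.

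Of the 27 measured genes of the AEC2 program, the surfactant and lamellar body genes and other markers of type 2 cells, 4 rose and 14 fell; adjusted over the list alone, 5 rose and 18 fell. The list was lower than other genes (camera, BH-adjusted p = 4.12e-05; adjusted p = 0.115 with an estimated correlation). SFTA2 fell most clearly by p, from 45.0 ± 4.16 to 16.1 ± 2.13 CPM. The surfactant protein A genes SFTPA1 and SFTPA2 fell by 1.55 and 1.87 on the log2 scale, although their near-identical sequences leave the split of reads between them uncertain. NAPSA, the aspartic protease that processes surfactant protein B, fell from 557.9 ± 18.2 to 258.6 ± 74.8 CPM (log2 change -1.11 ± 0.160). LAMP3, a membrane protein of the lamellar body, fell by 0.82, and SLC34A2, the phosphate transporter of these cells, by 0.74. NKX2-1, the lung lineage transcription factor, rose by 0.44 ± 0.0881, with 12.7% of its exon length shared with an antisense gene. The LAMP3 call was lost without WT library 1 (BH-adjusted p = 0.0767) or 2 (0.0775) and in a fit of only the 6 libraries compared (0.0604), and that of SLC34A2 without WT library 2 (0.0676) or E690K library 3 (0.0615), all in edgeR.

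Genes of lipid synthesis fell. Of 25 cholesterol synthesis genes, 0 rose and 16 fell, 19 adjusted over the list alone (camera, BH-adjusted p = 4.66e-09; adjusted p = 0.115 with an estimated correlation). They included the sterol oxidase MSMO1 (-1.04 ± 0.108), the sterol sensor INSIG1 (-0.87 ± 0.100) and HMGCS1 (-0.84 ± 0.120), which makes the mevalonate precursor. Of 28 fatty acid and phospholipid synthesis genes, 1 rose and 11 fell, or 1 and 16 adjusted over the list alone and 1 and 17 without E690K library 3 (camera, BH-adjusted p = 4.88e-07; adjusted p = 0.0835 with an estimated correlation). DGAT2, which makes triglyceride, fell by 1.29, ACSL4 by 0.79, and the desaturase SCD from 7047 ± 299 to 3861 ± 489 CPM.

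Several organelle and stress lists also moved down. Of 34 lysosome genes, 0 rose and 19 fell, or 2 and 22 adjusted over the list alone and 1 and 24 without E690K library 3 (camera, BH-adjusted p = 2.27e-08; adjusted p = 0.0789 with an estimated correlation), among them CD63 (-0.85), the cathepsin CTSS (-0.82) and the sialidase NEU1 (-0.70). Of 25 genes of the unfolded protein response, 0 rose and 14 fell, 18 adjusted over the list alone (camera, BH-adjusted p = 2.27e-08; adjusted p = 0.0835 with an estimated correlation), with MANF at -0.64, HERPUD1 at -0.90 and the chaperone DNAJB9 at -0.62. Of 20 genes of the NRF2 list, 0 rose and 10 fell, 11 adjusted over the list alone (camera, BH-adjusted p = 2.44e-05; adjusted p = 0.0835 with an estimated correlation). The ferritin light chain FTL fell from 3333 ± 194 to 1951 ± 166 CPM and the aldo-keto reductase AKR1C2 by 0.61. Of 16 antigen presentation genes, 0 rose and 6 fell under either adjustment, over all genes or over the list alone, or 1 and 8 without E690K library 3 (camera, BH-adjusted p = 0.00419; adjusted p = 0.212 with an estimated correlation), including B2M (-0.55).

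Neuroendocrine, progenitor and airway markers rose in E690K. All 10 lung neuroendocrine markers rose, also when adjusted over the list alone (camera, BH-adjusted p = 2.8e-11; adjusted p = 0.0789 with an estimated correlation). The median change of the list was 4.42, or 3.82 with genes at 0 counts in WT set to their bound. The granins SCG2 and CHGA were 38.1-fold and 30.5-fold higher. CHGA lay at 1.85, 0.448 and 0.273 CPM in WT libraries 1, 2 and 3 and at 16.8, 10.7 and 47.0 CPM in the E690K libraries, and its log2 change of 4.93 was 6.10 without WT library 1 and 4.08 without E690K library 3. PCSK1 and the neuropeptide gene CALCA reached 10.5 ± 1.75 and 10.6 ± 0.434 CPM, so these transcripts remained far below SFTPB. Of 14 lung progenitor markers, 9 rose and 0 fell, the same counts as adjusted over the list alone (camera, BH-adjusted p = 9.12e-05; adjusted p = 0.0835 with an estimated correlation), among them MYCN (1.44 ± 0.166), TESC (1.37 ± 0.179) and SOX4 (1.18 ± 0.157). Of 10 measured airway markers, 6 rose and 1 fell under either adjustment, including the list alone, or 6 and 2 without E690K library 3 (camera, BH-adjusted p = 0.00848; adjusted p = 0.089 with an estimated correlation). The secretoglobin gene SCGB3A2 rose from 4.24 ± 0.427 to 27.9 ± 3.57 CPM, and TPPP3, a marker of ciliated cells, by 1.80.

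Cell cycle and immediate early genes rose as well, and a part of the Wnt, Notch and Hippo targets. Of 30 proliferation genes, 18 rose and 0 fell, 25 adjusted over the list alone (camera, BH-adjusted p = 1.43e-10; adjusted p = 0.0835 with an estimated correlation). Examples were CENPF (0.78 ± 0.0846), the kinesin KIF11 (0.72) and the cyclin-dependent kinase CDK1 (0.72). Of 18 immediate early genes, which also respond to dissociation and sorting, 10 rose and 0 fell, 11 adjusted over the list alone (camera, BH-adjusted p = 1.22e-07; adjusted p = 0.093 with an estimated correlation), led by the nuclear receptor NR4A1, at 38.2 ± 1.10 CPM in WT and 100.1 ± 4.74 in E690K. Of 17 Wnt targets, 6 rose, 9 adjusted over the list alone and 10 without E690K library 3 (camera, BH-adjusted p = 0.00132; adjusted p = 0.472 with an estimated correlation), and of 15 Notch and Hippo targets, 6 rose under either adjustment, including the list alone (camera, BH-adjusted p = 0.00383; adjusted p = 0.208 with an estimated correlation). The Wnt-responsive receptor TNFRSF19 rose by 1.05 and the Hippo target ANKRD1 by 1.17.

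Liver-type transcripts were present in WT and lower in E690K. Of 18 hepatic and yolk sac markers, 0 rose and 11 fell, 14 adjusted over the list alone (camera, BH-adjusted p = 8.54e-13; adjusted p = 0.0835 with an estimated correlation). The fibrinogen genes FGA, FGB and FGG fell by 2.13, 2.41 and 2.36, and TF, which encodes transferrin, fell from 828.0 ± 54.0 to 188.6 ± 10.4 CPM. RBP4 fell by 2.07. The median change of 6 liver-restricted members, the apolipoproteins APOA1, APOA2, APOB and APOC3 with ALB and AHSG, was -0.58. Other genes with large changes were CCDC154 (4.10 ± 0.214), GUCY1A2, a subunit of soluble guanylate cyclase (2.88 ± 0.158), and the long noncoding RNA MIAT (2.76, with 1.9% of its exon length shared with MIATNB) on the higher side. On the lower side were the lysosomal glycoprotein CD68 (-2.35), the cytokine receptor CSF3R (-2.34) and the complement gene C2 (-2.18).

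The mitochondrially encoded list was lower than other genes in E690K (camera, BH-adjusted p = 0.0214; adjusted p = 0.722 with an estimated correlation), while 0 of its 13 genes were called in edgeR, DESeq2 or limma voom (0, 0 and 1 at an unadjusted p under 0.05). Without E690K library 3, the library low in these transcripts, the camera adjusted p was 0.727 (BH), with 1 gene higher and 1 lower. The heat shock list (0 higher and 5 lower of 13, also over the list alone) and the autophagy list (0 and 2 of 17, also over the list alone) were not called (camera, BH-adjusted p = 0.12 and 0.104), but were without E690K library 3 (0.00936 with 8 lower, and 0.0157 with 6 lower; 0.13 and 0.185 in that fit with an estimated correlation). The heat shock median was 4.88e-05 where the mean was -0.157 and camera placed it on the lower side. FGF targets (3 higher and 1 lower of 17, also over the list alone) and the transitional epithelial list (5 and 5 of 19, or 6 and 5 over the list alone) were not called either (camera, BH-adjusted p = 0.589 and 0.97). Without E690K library 3, their counts were 6 and 2, and 6 and 8. The transitional median was -0.063 where the mean was 0.0257 and camera placed it on the higher side. Across the 35 tested lists, 19 were called, 9 higher and 10 lower, with camera at the preset correlation.

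**Figure D2:**
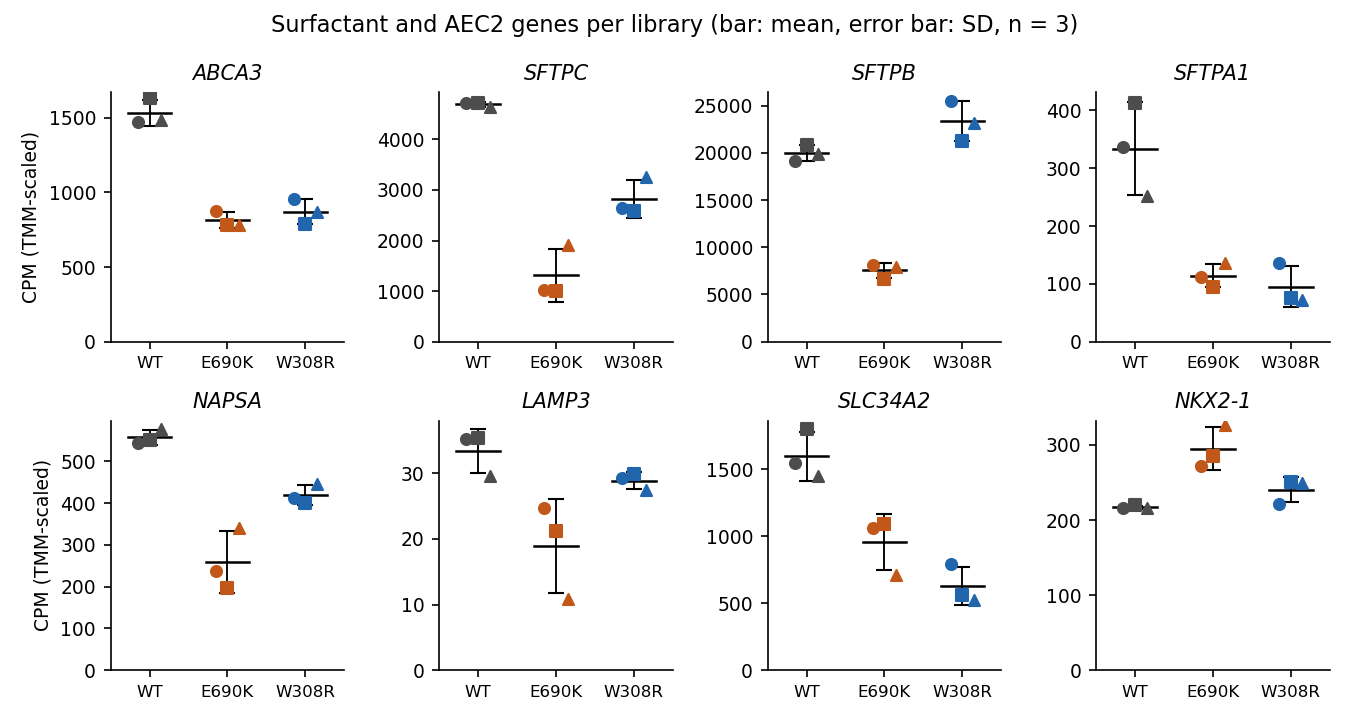
Points show TMM-normalised CPM per library for 8 genes of the type 2 cell program, on axes that start at 0, with the mean (bar) and SD (error bar) of the 3 libraries of each genotype. ABCA3, SFTPC, SFTPA1 and SLC34A2 were lower than WT in both mutants, while SFTPB was 19980 in WT, 7547 in E690K and 23340 in W308R.

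W308R against WT. The W308R cells also had less ABCA3 transcript, and their surfactant protein A genes were lower, but SFTPB was not. Cell cycle, glycolytic and senescence-associated genes were higher, and liver-type transcripts lower. With an estimated correlation (camera), the glycolytic and liver-type calls were lost (BH-adjusted p = 0.0807 and 0.0777), and all 4 were lost when E690K library 3 was also left out (0.105 to 0.153). ABCA3 fell from 1530 ± 86.6 to 871.5 ± 83.7 CPM (log2 change -0.81 ± 0.0996). SFTPB was at 23340 ± 2110 CPM against 19980 ± 864 in WT and was not called (edgeR, BH-adjusted p = 0.234). MYH14, which encodes a non-muscle myosin heavy chain, and MGMT, which encodes a DNA repair enzyme, had 0 counts in all 3 W308R libraries. They were at least 722-fold and at least 144-fold lower than in WT, with a floor of 3 counts per library.

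Of 17233 genes, 1652 rose and 1508 fell (edgeR, BH-adjusted p under 0.05), 358 and 461 of them by more than 2-fold; groups did not overlap for 44.8% of genes, where chance gives 10%. The count was 1701, 1679 and 1908 without WT library 1, 2 or 3, 1843 and 1888 without W308R library 2 or 3, 5742 without E690K library 3, which enters the shared estimate of the spread, and 5200 in a fit of only the 6 libraries compared.

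Of the 27 AEC2 program genes, 2 rose and 7 fell, or 3 and 11 adjusted over the list alone and 4 and 12 without E690K library 3 (camera, BH-adjusted p = 0.02; adjusted p = 0.4 with an estimated correlation). SFTPA1 and SFTPA2 fell by 1.82 and 2.10 on the log2 scale, and SLC34A2 by 1.35. SFTPC fell by 0.73 ± 0.214, from 4693 ± 47.9 to 2829 ± 377 CPM. This call was lost in edgeR without any of the 6 libraries compared, left out in turn, with BH-adjusted p between 0.0575 (without W308R library 3) and 0.127 (without W308R library 2). NAPSA (-0.41), LAMP3 (-0.21) and NKX2-1 (0.15) were not called. NAPSA was called in edgeR with only the 6 libraries compared (BH-adjusted p = 0.000173), without E690K library 2 (0.0399) or without E690K library 3 (0.000373), and SFTPB, higher, with only those 6 (0.0225). Cholesterol synthesis counted 0 genes higher and 6 lower of 25, 8 adjusted over the list alone and 13 without E690K library 3 (camera, BH-adjusted p = 0.000933; adjusted p = 0.4 with an estimated correlation), with HSD17B7 at -0.93 ± 0.118.

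Among the 35 tested lists, proliferation genes rose most broadly. Of 30, 26 rose and 0 fell, 27 adjusted over the list alone (camera, BH-adjusted p = 6.53e-24; adjusted p = 0.0382 with an estimated correlation). UBE2C, which encodes a ubiquitin-conjugating enzyme of mitosis, rose from 51.6 ± 4.40 to 119.3 ± 4.05 CPM, and KIF11 by 0.95 ± 0.0814. The spindle gene TPX2 rose by 1.40 ± 0.100; it lies in a stretch of chromosome 20 whose 33 measured genes had a median change of 0.54 in W308R. Of 25 hypoxia and glycolysis genes, 20 rose and 0 fell, 23 adjusted over the list alone (camera, BH-adjusted p = 1.28e-16; adjusted p = 0.0807 with an estimated correlation). The glucose transporter SLC2A1 rose from 259.7 ± 34.7 to 688.1 ± 45.7 CPM, the glycolytic regulator PFKFB4 by 1.32 and the peptide hormone gene ADM by 1.36. Of 16 senescence-associated genes, 12 rose and 0 fell, 13 adjusted over the list alone (camera, BH-adjusted p = 2.1e-08; adjusted p = 0.0247 with an estimated correlation). Its members that moved were of different kinds. CDKN1C (2.15 ± 0.134) is an inhibitor of cyclin-dependent kinases, and IGFBP5 (1.56 ± 0.181) a binding protein for insulin-like growth factors. The chromatin protein HMGB2 (0.98 ± 0.0909) is abundant in cycling cells, so a rise of this list does not by itself show senescence.

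Further lists on the higher side included the transitional epithelial state, with 6 of 19 genes higher and 0 lower, 7 adjusted over the list alone and 12 without E690K library 3 (camera, BH-adjusted p = 0.00126; adjusted p = 0.228 with an estimated correlation). Its examples were S100A6 (0.85), ANXA1 (0.82) and the keratin KRT17 (1.79 ± 0.256). Of 18 immediate early genes, 12 rose and 0 fell, also when adjusted over the list alone (camera, BH-adjusted p = 2.1e-08; adjusted p = 0.143 with an estimated correlation), with NR4A1 at 1.28 and FOSB at 0.73. FGF signaling targets had 7 of 17 higher, or 7 higher and 1 lower adjusted over the list alone and also without E690K library 3 (camera, BH-adjusted p = 0.0184; adjusted p = 0.4 with an estimated correlation), among them the phosphatase DUSP5 (0.96). TGF-beta and matrix genes had 8 of 23 higher, or 10 higher and 2 lower adjusted over the list alone and 11 and 4 without E690K library 3 (camera, BH-adjusted p = 0.02; adjusted p = 0.243 with an estimated correlation), among them THBS1 (0.86). Of 10 airway markers, 5 rose and 0 fell, or 5 and 1 adjusted over the list alone (camera, BH-adjusted p = 0.0184; adjusted p = 0.163 with an estimated correlation), with SCGB3A2 at 1.02 and FOXJ1, the transcription factor of ciliated cells, at 1.32. The neuroendocrine list, with all 10 members higher in E690K, had 5 of 10 higher here under either adjustment, including the list alone (camera, BH-adjusted p = 0.0184; adjusted p = 0.4 with an estimated correlation).

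Liver-type transcripts fell. Of 18 hepatic and yolk sac markers, 16 fell and 0 rose, the same counts as adjusted over the list alone (camera, BH-adjusted p = 3.66e-16; adjusted p = 0.0777 with an estimated correlation). TF fell from 828.0 ± 54.0 to 224.7 ± 11.2 CPM, FGG by 2.38 and FGA from 380.8 ± 9.62 to 134.4 ± 18.2 CPM. APOB and APOA2 fell by 3.19 and 3.11, and the median of the 6 liver-restricted members was -2.53. Heat shock genes had 1 higher and 5 lower of 13, or 1 and 6 adjusted over the list alone and 1 and 8 without E690K library 3 (camera, BH-adjusted p = 0.00202; adjusted p = 0.243 with an estimated correlation), with DNAJA1 at -0.92, HSPH1 at -0.79 and HSPA8 at -0.53. Of 17 autophagy genes, 4 fell, also adjusted over the list alone, and 8 without E690K library 3 (camera, BH-adjusted p = 0.0317; adjusted p = 0.249 with an estimated correlation). That call was lost in camera without WT library 2 (BH-adjusted p = 0.0761), WT library 3 (0.0626) or W308R library 2 (0.0828). Without E690K library 3, the mitochondrially encoded list (9 of 13 lower) and the nuclear oxidative phosphorylation list (7 higher and 1 lower of 24) were also called (camera, BH-adjusted p = 0.000283 and 0.00575; 0.587 and 0.59 in that fit with an estimated correlation; 0.612 and 0.0629 with all libraries). Across the 35 lists, 14 were called, 9 higher and 5 lower, and 2 with an estimated correlation (senescence and proliferation); without E690K library 3 that count was 0.

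The highest named changes were IGF2 (2.51 ± 0.172), an imprinted growth factor gene with 4.8% of its exon length shared with an antisense gene, PGF (2.37), LDOC1 (2.27), CDKN1C (2.15) and STC1 (2.09). MYEOV (2.07), FAM167A (1.93) and KISS1R (1.86) followed. Besides MYH14 and MGMT, the lowest were CEBPZOS (-4.61 ± 0.186), with 7.5% of its exon length shared with CEBPZ on the opposite strand, JRK (-4.39 ± 0.294), CCDC125 (-4.34 ± 0.167), APOB (-3.19) and LCP1 (-3.16), an actin-bundling protein of blood cells. MYH14 (chr19 50188186 to 50310544) was at 55.7 ± 2.74 CPM in WT, MGMT (chr10 129467184 to 129768007) at 11.1 ± 0.550, JRK (chr8 142657460 to 142681968) at 10.9 ± 0.486 and CCDC125 (chr5 69280175 to 69332809) at 10.2 ± 0.612. None of these 4 genes shares exon length with another of the 17233 measured genes. Overlap with genes outside that set was not checked.

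**Figure D3:**
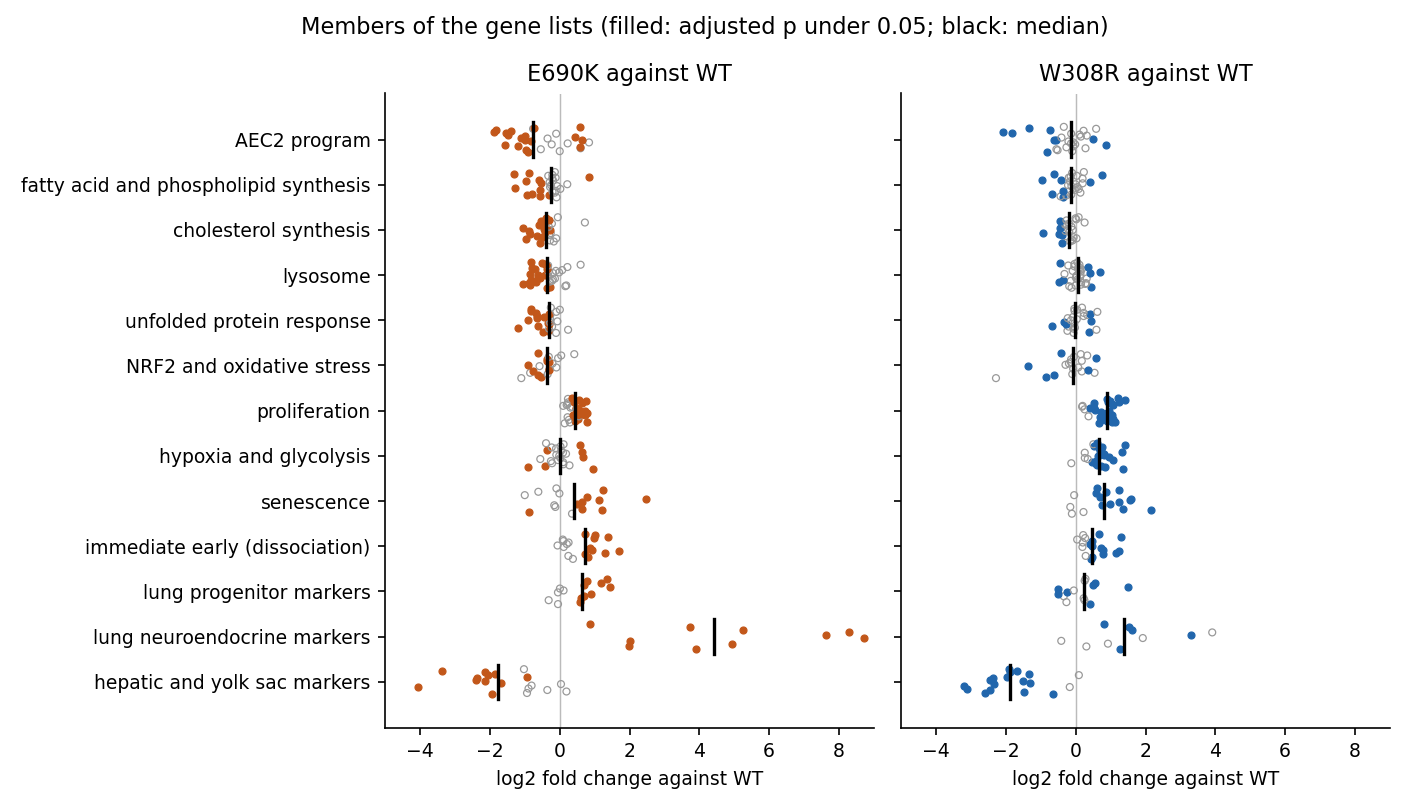
Each point is a measured member of a gene list, placed by its log2 fold change against WT in E690K (left) or W308R (right) and filled where the gene was called (edgeR, BH-adjusted p under 0.05); black marks are list medians. The neuroendocrine list has its largest median in E690K (4.42), and the hepatic and yolk sac list is low in both mutants (-1.77 and -1.90).

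W308R against E690K. The direct comparison asked where the mutant lines differ. ABCA3 did not differ detectably, at 871.5 ± 83.7 and 815.5 ± 53.4 CPM (log2 change 0.10 ± 0.099; edgeR, BH-adjusted p = 0.533). SFTPB was 3.09-fold higher in W308R (23340 ± 2110 against 7547 ± 830 CPM), SFTPC 2.15-fold higher and NAPSA 1.63-fold higher. Neuroendocrine and progenitor genes were lower in W308R, and lysosomal, protein folding, glycolytic and antigen presentation genes were higher. These are calls at a preset correlation (camera); 0 of 35 lists were called with an estimated correlation (8 at an unadjusted p under 0.05; 17 with fry).

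Of 17233 genes, 1968 were higher and 1885 lower in W308R (edgeR, BH-adjusted p under 0.05), 353 and 509 of them by more than 2-fold; groups did not overlap for 37.1% of genes, where chance gives 10%. The count was 5832 without E690K library 3, 2197 without W308R library 3 and 2489 in a fit of only these 6 libraries. E690K libraries 1 and 2 and W308R library 1 had negative trends of expression with transcript GC content, and the other 3 mutant libraries positive ones; with that side as a term in the 6 libraries, 4633 genes were called, 3478 of them shared with the 3853.

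In the AEC2 program, 10 of 27 genes were higher and 6 lower, or 12 and 6 adjusted over the list alone, and the list was not called (camera, BH-adjusted p = 0.131). SFTA2 was at 48.6 ± 4.23 against 16.1 ± 2.13 CPM. PGC, which encodes pepsinogen C, was higher by 1.32 and CXCL17, a chemokine of mucosal epithelia, by 2.45 ± 0.260. SFTPA1 (-0.27) and LAMP3 (0.61) were not called. SLC34A2 (-0.61) and NKX2-1 (-0.30) were lower. In edgeR, the SLC34A2 call was lost without WT library 1 (BH-adjusted p = 0.0553), WT library 3 (0.0502), E690K library 1 (0.0915) or 2 (0.108), W308R library 2 (0.13) or 3 (0.147), or with only the 6 libraries (0.078). The NKX2-1 call was lost in edgeR without WT library 1 (BH-adjusted p = 0.0566), 2 (0.0573) or 3 (0.0551), E690K library 2 (0.0553), W308R library 1 (0.0915), 2 (0.0593) or 3 (0.0709), or with only the 6 libraries (0.0974). LAMP3 was called under several settings (edgeR without E690K library 3, BH-adjusted p = 0.0164; without E690K library 1, 0.0207).

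Lysosome genes were higher in W308R in 20 of 34 cases and lower in 1, or 22 and 2 adjusted over the list alone (camera, BH-adjusted p = 2.39e-09; adjusted p = 0.0611 with an estimated correlation). CD63 was at 997.3 ± 54.8 against 498.5 ± 12.7 CPM, NEU1 higher by 0.87 and the cathepsin CTSB by 1.18. Of 25 unfolded protein response genes, 14 were higher and 0 lower, 15 adjusted over the list alone (camera, BH-adjusted p = 1.33e-07; adjusted p = 0.0848 with an estimated correlation), with CALR, MANF and PDIA4 at 0.87, 0.87 and 0.71. Of 28 fatty acid and phospholipid genes, 12 were higher and 3 lower, or 13 and 4 adjusted over the list alone and 14 and 5 without E690K library 3 (camera, BH-adjusted p = 0.00137; adjusted p = 0.257 with an estimated correlation). PLIN2, which coats lipid droplets, was at 486.3 ± 31.0 against 249.9 ± 3.95 CPM. Of 25 cholesterol synthesis genes, 7 were higher and 1 lower, or 8 and 1 adjusted over the list alone and 14 and 1 without E690K library 3 (camera, BH-adjusted p = 0.00145; adjusted p = 0.504 with an estimated correlation).

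Of 25 hypoxia and glycolysis genes, 18 were higher in W308R and 0 lower, 22 adjusted over the list alone (camera, BH-adjusted p = 4.02e-14; adjusted p = 0.088 with an estimated correlation), including the phosphofructokinase PFKP (1.08 ± 0.091) and the aldolase ALDOC (1.15 ± 0.112). Of 16 antigen presentation genes, 8 were higher and 0 lower, 9 adjusted over the list alone (camera, BH-adjusted p = 0.000241; adjusted p = 0.202 with an estimated correlation). Proliferation genes were higher in 16 of 30 cases, 17 adjusted over the list alone (camera, BH-adjusted p = 1.33e-07; adjusted p = 0.181 with an estimated correlation), and senescence-associated genes in 9 of 16 with 2 lower, or 10 and 2 adjusted over the list alone (camera, BH-adjusted p = 0.000596; adjusted p = 0.0848 with an estimated correlation), led by CDKN1A (1.09), the p21 inhibitor of cell cycle kinases. The transitional list had 9 of 19 higher and 4 lower, or 11 and 4 adjusted over the list alone (camera, BH-adjusted p = 0.0371; adjusted p = 0.41 with an estimated correlation). That call was lost in camera without E690K library 1 (BH-adjusted p = 0.0526) or 2 (0.072), without W308R library 1 (0.0928), and with the GC side as a term (0.0654). KRT17 was 7.83-fold higher in W308R.

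Of 10 neuroendocrine markers, 9 were lower in W308R and 0 higher, also adjusted over the list alone (camera, BH-adjusted p = 4.01e-09; adjusted p = 0.0848 with an estimated correlation), with SCG2 at -3.64 ± 0.307 and CALCA at -1.67 ± 0.149. Of 14 progenitor markers, 2 were higher and 8 lower, or 2 and 9 adjusted over the list alone (camera, BH-adjusted p = 0.00137; adjusted p = 0.181 with an estimated correlation). CPM, the surface protein used for the day 30 sort, was at 634.2 ± 52.2 CPM in W308R and 1148 ± 58.8 in E690K, and HMGA2 was lower by 1.04. The hepatic list went both ways, with 6 of 18 higher and 7 lower (7 and 7 adjusted over the list alone), and was not called (camera, BH-adjusted p = 0.747); its median was -0.03, while camera placed it on the higher side. RBP4 was 2.16 ± 0.108 higher and AFP 1.28 higher in W308R, and ALB 1.68 lower (log2 change -1.68 ± 0.184). The remaining highest genes were IGF2 (3.27 ± 0.178), the lipoxygenase gene ALOX15B (2.98) and MYEOV (2.85). The lowest were MYH14, at least 1760-fold lower in W308R, MGMT, at least 151-fold lower, JRK (-4.58), CCDC125 (-4.53) and CEBPZOS (-4.20). Without E690K library 3, the mitochondrially encoded list (7 of 13 lower) and the nuclear oxidative phosphorylation list (10 higher of 24) were also called (camera, BH-adjusted p = 0.00109 and 0.000852; 0.592 and 0.497 in that fit with an estimated correlation; 0.124 and 0.232 with all libraries). Across the 35 lists, 13 were called, 11 higher and 2 lower with camera at the preset correlation.

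**Figure D4:**
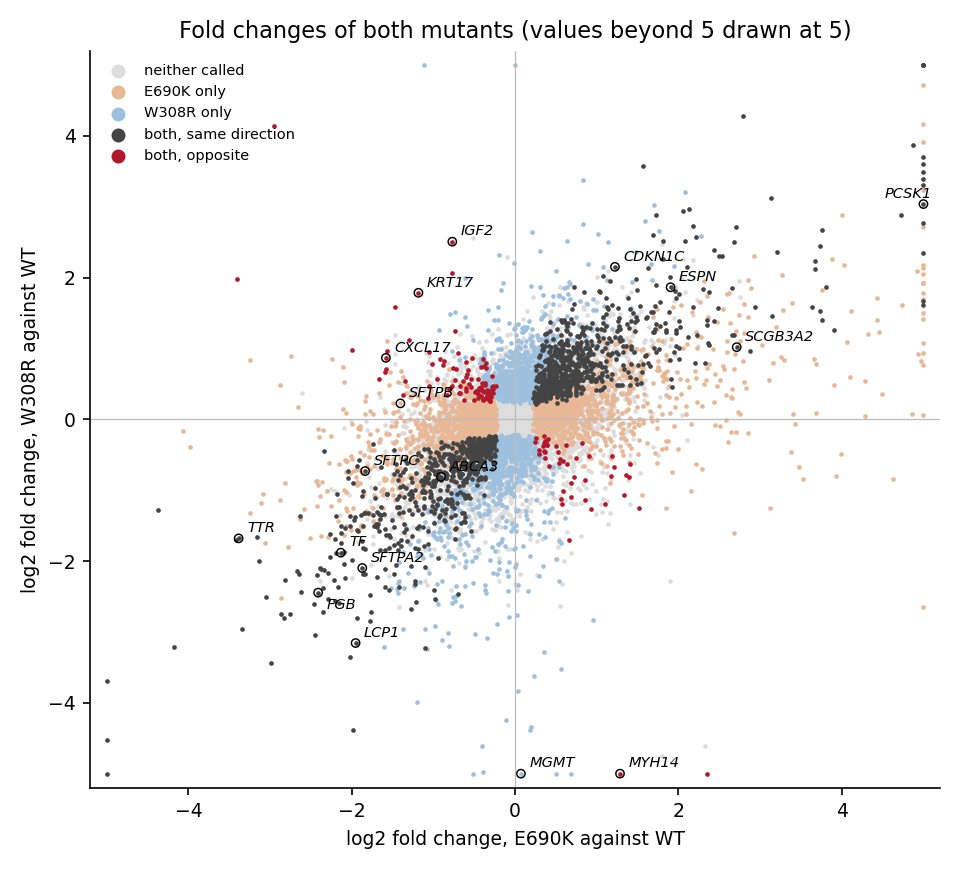
Each point is a gene, with its log2 fold change in E690K against WT on the horizontal axis and in W308R against WT on the vertical axis, clipped at 5 in either direction and coloured by the calls. Genes called in the same direction in both mutants (1253) lie along the diagonal, and those called in opposite directions (139) off it.

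Shared change of the mutants. Both mutants were lower than WT in the fibrinogen genes FGB (-2.41 ± 0.199 in E690K and -2.45 ± 0.199 in W308R) and FGG (-2.36 and -2.38), in LCP1 (-1.95 and -3.16), in TF (-2.13 and -1.88) and in SFTPA2 (-1.87 and -2.10). ESPN, an actin-bundling protein of microvilli, was higher in both (1.90 and 1.86), with 5.5% of its exon length shared with TNFRSF25. In all, 675 genes were called higher and 578 lower in both, where independent lists would overlap in 186 and 162 genes, and 139 were called in opposite directions. The simulations of unchanged groups gave 0 such calls, which tests little, since unchanged groups have almost no calls to share. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.521 and a Spearman rho of 0.472. Simulated groups that share the WT libraries gave 0.489 and 0.452. The same sign was found for 66.0% of genes, against 66.5% in the simulations. Unchanged groups that share a control reach such values by construction, so r, rho and the sign share cannot decide whether change is shared. The covariance was 0.235 against a simulated 0.0442, a difference of 0.191. The 3 WT libraries cannot be split into parts of at least 2, so part of the excess of these values may come from the shared controls. The shared count was 650, 614 and 679 without WT library 1, 2 or 3, 2208 without E690K library 3 and 790 without W308R library 2.

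The EGFP line of the table gives the transcript of the reporter fused to ABCA3. It was chosen after its values were seen. EGFP counts per 100 ABCA3 counts were 9.26 ± 0.291 (SD, n = 3) in WT and 13.2 ± 0.306 (n = 3) in W308R, with a 2-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. In E690K the ratio was 12.1 ± 3.99, from 9.62, 9.90 and 16.7 in libraries 1, 2 and 3, with a 2-sided exact permutation p of 0.1 against WT and 0.7 against W308R. The line itself was lower in E690K than in WT (-0.54 ± 0.168; edgeR, BH-adjusted p = 0.0397) and not called in W308R (-0.30; edgeR, BH-adjusted p = 0.253). The E690K call was lost in edgeR with only the 6 libraries (BH-adjusted p = 0.084) and without any library, left out in turn, apart from E690K library 3 and W308R library 1, and W308R was called without E690K library 3 (0.01) or with only the 6 libraries compared (0.0145).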

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

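The tests of GC and length trends, of overlapping genes, of further neuroendocrine genes and of other splits of the libraries were fixed before their results were seen, while the tests of cell types in E690K library 3, of neighbouring genes, of the clone, of liver-restricted genes and of the share of iAEC2s were chosen only after the result was seen.

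The mutants moved in opposite directions from WT in 139 genes whose difference between the mutants was itself called (edgeR, BH-adjusted p under 0.05). MYH14 was 1.29 higher on the log2 scale in E690K than in WT and had 0 counts in W308R, where it was at least 1760-fold lower than in E690K (fitted log2 change -15.43). IGF2 changed by -0.77 in E690K and 2.51 in W308R, a difference of 3.27. ALOX15B was lower in E690K and changed by 0.98 in W308R, a difference of 2.98. KRT17 changed by -1.18 and 1.79, a difference of 2.97. MYEOV changed by -0.78 and 2.07, a difference of 2.85. CXCL17 changed by -1.58 and 0.87, a difference of 2.45. These differences were tested in the comparison of W308R with E690K.

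E690K library 3 stood apart from the other E690K libraries, with 1.28% mitochondrially encoded counts against 7.88% and 7.78%. Its 13 mitochondrially encoded genes deviated from the mean of libraries 1 and 2 by a median of -2.57 (log2), and by -2.54 after trends with GC content and transcript length were removed. Those trends accounted for 15.6% of the variance of its deviations, so they argue against being the whole cause. The AEC2 program deviated by a median of 0.0466, with its 26 genes between -1.24 and 1.02. This argues against cells of another type in place of most iAEC2s. It cannot decide on a smaller change of the cell mix, since the limit set for the median was -1. The deviations of E690K library 3 also went with gene body length (Spearman rho -0.251, against 0.0137 for library 1 minus library 2). A difference in RNA or its preparation, with a lower yield of mitochondrial transcripts, may therefore remain. No further biological explanation was tested, since the library shares its genotype with the others.

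In W308R, 4 genes were near absent (CCDC125, JRK, MGMT and MYH14), against 0 in E690K and 0 in WT by the same rule. The rule asked for a mean of at least 5 CPM in both other groups, and for 5% or less of the lower of them. Misassigned reads at overlapping measured genes are argued against, as 0 of the 4 share over 10% of their exon length with another measured gene. Overlap with genes that were not measured was not checked, so it stays open. Loss of a segment that reaches the neighbouring genes is argued against for CCDC125 and MGMT, whose nearest measured genes (CDK7, AK6, MKI67 and GLRX3) had a median change of -0.0517. It stays open for JRK and MYH14, whose neighbours had a median of -0.869, with LY6E at -3.70 but TSNARE1 at -0.03 and ZNF473 at 0.17. A property of the clone cannot be told apart from the substitution, since each genotype is 1 clone and the only value at hand is the count of 0 in E690K; a small deletion or silencing in the clone is a hypothesis that needs DNA data.

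Markers of other cell types moved in the sorted E690K cells, with the neuroendocrine list at a median of 4.42 and the hepatic list at -1.77. A lower share of iAEC2s was tested by whether all other types rose alike, and the hepatic list, at -1.77, did not rise. This cannot decide, since a single other type could take their place. Bulk counts also do not show which cells make the liver-type transcripts. The liver-restricted genes (ALB, APOA1, APOA2, APOB, APOC3 and AHSG) had a median of -0.581 where TTR changed by -3.39. They were picked after the result was seen, and FGA, FGB, FGG and TF of the same list fell further than that median. They therefore cannot decide whether there were fewer hepatic-like cells. A further list of 25 neuroendocrine genes, written before their values were looked at, had 16 of 23 measured genes higher and 2 lower, with a median of 2.03, and 0% of 10000 random lists matched on expression reached it. This is consistent with neuroendocrine cells, which the sort for GFP on ABCA3 would be predicted to remove, or with such a program in part of the iAEC2s, at levels far below the surfactant genes (CHGA 24.9 and SFTPB 7547 CPM on average), and bulk counts cannot tell these cases apart.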

How the results depend on the processing

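The fits with GC and length offsets, with the GC-slope side as a term, and without E690K library 3 at an estimated correlation were chosen only after the data were seen; the other alternatives were set beforehand. Counts of genes stayed within 1.5 times the reported value under DESeq2 (4476 for E690K against WT, 3872 for W308R against WT, 4548 for W308R against E690K, 6981 jointly), limma voom, other scaling factors, a filter of 1 CPM in 3 libraries, the fit without mitochondrially encoded genes, and GC and length offsets (4117, 3486 and 3938). Of the reported genes, in the order of the comparisons, DESeq2 called 99.9%, 99.9% and 99.9% in the same direction, the offsets 86.1%, 91.6% and 78.4%, and a replicate block 89.6%, 88.4% and 91.6%. Leaving out the low-count filter removed and added 0 genes, so it tests nothing. A fit of only the 6 libraries compared, which estimates the spread from them alone, gave 5200 genes for W308R against WT and 2489 for W308R against E690K. How much of the change comes from the spread was not tested. With each library left out in turn, the counts ranged from 2278 to 5424 for E690K against WT, from 1679 to 5742 for W308R against WT, from 2197 to 5832 for W308R against E690K, from 4208 to 8658 jointly, and from 614 to 2208 for genes shared by the mutants. The highest count of each came without E690K library 3. Fewer libraries lower the power by construction. E690K library 3 enters the shared estimate of the spread and lies far from its replicates. The lowest correlation within E690K was 0.9776, against 0.9926 between libraries 1 and 2. Leaving it out also raised the count for W308R against WT, which compares no E690K library. How much of the rise comes from the spread was not tested.

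The numbers of lists called by camera fell from 19, 14 and 13 to 0, 2 and 0 with an estimated correlation (14, 7 and 8 at an unadjusted p under 0.05; 21, 15 and 17 with fry), and to 0, 0 and 0 when E690K library 3 was also left out. A correlation above the preset 0.01 cannot be the whole cause. The senescence list in W308R against WT had an estimated correlation of -0.0104, and its unadjusted camera p still went from 3e-09 to 0.000706. The airway list in E690K against WT, at -0.0658, went from 0.00363 to 0.0229. What else contributes was not tested. Of 355 results for named genes, 297 kept their direction and their side of the threshold in every alternative, and 0 were reversed; of 46 results for lists, 0 did so in every alternative, and 0 were reversed. With a replicate block, 3568, 2952 and 3702 genes were called in the 3 comparisons, 5557 jointly and 1133 in both mutants, with 19, 14 and 14 lists. The numbers are not known to pair libraries: deviations of same-numbered libraries correlated between -0.0826 and 0.123, and 3 of 9 libraries correlated best with their own number. In simulated data of this depth and number of libraries, 49.3% of 1.5-fold changes in E690K were recovered; depth was not varied, so its part in this is not known.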

Other observations

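The tests of whole autosomes, of the chromosome 20 segment between the mutants and of imprinted genes were chosen only after the result was seen, while the test of windows of 50 genes and the tests of other splits of the libraries were written before.

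Several lists were called in E690K against WT or between the mutants and are not described above. Sterol efflux genes had 1 higher and 4 lower of 13 in E690K, the same adjusted over the list alone (camera, BH-adjusted p = 0.0104; 0.116 with an estimated correlation), with APOC1 at -0.92 and the phospholipid transfer gene PLTP at -1.12. Senescence-associated genes had 8 higher and 1 lower of 16 in E690K, or 9 and 2 over the list alone and 8 and 2 without E690K library 3 (camera, BH-adjusted p = 0.0431; 0.125 with an estimated correlation; 0.0711 without WT library 2), with IGFBP7 at 2.48. TGF-beta and matrix genes had 11 higher and 3 lower of 23 in E690K, or 11 and 5 over the list alone and also without E690K library 3 (camera, BH-adjusted p = 0.0431; 0.212 with an estimated correlation), with TNC at -1.80 and COL4A1 at 1.59. That call was lost with the 1 CPM filter (0.0575) and without WT library 2 (0.0542), E690K library 1 (0.0556) or 2 (0.0586), or W308R library 3 (0.0527). Integrated stress response genes had 8 of 23 higher and 1 lower in W308R than in E690K, or 11 and 1 over the list alone (camera, BH-adjusted p = 0.000748; 0.544 with an estimated correlation; 0.0695 with fry), with ALDH1L2 at 1.77. In E690K against WT, 6 of them fell (camera, BH-adjusted p = 0.0798), and without E690K library 3 there were 2 higher and 7 lower and the list was called (0.0157; 0.627 in that fit with an estimated correlation). NRF2 genes had 6 of 20 higher and 1 lower in W308R than in E690K, or 7 and 1 over the list alone and 6 and 2 without E690K library 3 (camera, BH-adjusted p = 0.00916; 0.257 with an estimated correlation).

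Other lists were not called by camera but had members that were. Among 11 genes of phospholipid-transporting ABC proteins, the family of ABCA3, ABCA8 rose from 2.74 ± 0.919 to 11.7 ± 0.844 CPM in E690K (log2 change 2.09 ± 0.237), and ABCG1 rose by 0.84, with 0 lower, or 2 lower without E690K library 3 (camera for the list, BH-adjusted p = 0.908). The ABCG1 call was lost without WT library 1 (edgeR, BH-adjusted p = 0.0822) or 2 (0.084). In W308R, ABCG1 rose by 1.19 and ABCA2 by 0.61, and ABCB4 fell by 0.93 (camera for the list, BH-adjusted p = 0.866). The ABCB4 call was lost without WT library 3 (edgeR, BH-adjusted p = 0.0673), W308R library 2 (0.0603) or 3 (0.0647). Of 18 markers of type 1 cells, 4 rose and 3 fell in E690K (camera, BH-adjusted p = 0.908), with TIMP3 going from 98.0 to 35.1 CPM on average and COL4A4 at 1.37. In W308R, 4 rose and 5 fell, or 7 and 5 without E690K library 3 (camera, BH-adjusted p = 0.794), with EMP2 at -0.58 and RTKN2 at 0.68. Of 21 interferon response genes, 1 rose and 3 fell in E690K, or 2 and 6 without E690K library 3 (camera, BH-adjusted p = 0.586), with IFITM1 at -1.84, BST2 at -2.25 and IFITM3 at -0.92. In W308R, 2 rose and 1 fell, or 3 and 3 without E690K library 3 (camera, BH-adjusted p = 0.849), with OAS3 at 1.03 and IFI27 at -0.92; median and mean were both -0.03 while camera placed the list on the higher side. The IFI27 call was lost in edgeR without any of the 6 libraries compared, left out in turn (BH-adjusted p between 0.0562 and 0.0913). Of 32 inflammatory genes, 9 rose and 4 fell in E690K, or 9 and 8 without E690K library 3 (camera, BH-adjusted p = 0.589), and the list median was -0.03 where the mean was 0.04 and camera placed it on the higher side.

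Among markers of cell types outside the lung epithelium, the intestinal list had 1 higher (CLDN2, 1.22) and 3 lower of 9 in E690K (camera, BH-adjusted p = 0.0765) and 0 higher and 3 lower in W308R, or 2 and 3 without E690K library 3 (camera, BH-adjusted p = 0.105). VIL1 of that list fell by 2.13 and 1.61. The mesenchymal list had 2 higher and 1 lower of 8 in E690K, or 2 and 2 without E690K library 3 (camera, BH-adjusted p = 0.985; median -0.07 and test on the lower side, mean 0.24). COL3A1 went from 0.504 to 3.04 CPM on average in E690K (2.58), while ACTA2 fell by 1.44. The endothelial and blood list had 1 higher (KDR, 1.11) and 1 lower (CD14, -1.01) of 5 in E690K (camera, BH-adjusted p = 0.662). In W308R it had 2 higher (KDR, 1.71, among them) and 2 lower (LYZ, -1.75, and CD14, -1.15; camera, BH-adjusted p = 0.989). The CD14 call was lost in edgeR in E690K without WT library 1 (BH-adjusted p = 0.107) or 3 (0.0805) or E690K library 1 (0.0593) or 3 (0.0528), and in W308R without WT library 1 (0.0815) or 3 (0.0594) or W308R library 1 (0.0586) or 3 (0.0604). Of the 4 pluripotency markers measured, too few to test, all rose in W308R, with DNMT3B at 0.98 and ZFP42 at 0.80.

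Genes were also ordered by position to look for gains or losses in the mutant lines. The autosome median farthest from 0 was 0.114, for chromosome 13 in E690K, which argues against gain or loss of a whole autosome in the cells at large. Of 12088 windows of 50 measured genes per line, the median farthest from 0 was 0.452, in W308R on chromosome 20 (23747553 to 34560345), where windows on other chromosomes reached 0.266 in W308R and 0.293 in E690K. Overlapping it and reaching past its end, the stretch where the running median over 11 genes of the change from WT stayed above 0.3 held 33 measured genes from BCL2L1 to PIGU (31664452 to 34698790), which include TPX2, ASXL1, DNMT3B and E2F1. Their median change of 0.539 from WT, with 32 genes higher and 23 called, follows in part from that choice. The medians per W308R library were 0.546, 0.490 and 0.528, the E690K median against WT was -0.00902, and the other 326 genes of the chromosome had a median of 0.0108 in W308R. Against E690K, which shares no control with the first comparison but has the same W308R libraries, the median was 0.541. This is consistent with a gain of part of chromosome 20 in the W308R clone. It remains a hypothesis that needs DNA data, and so TPX2, E2F1 and DNMT3B may owe part of their change to the clone and not to the substitution.

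IGF2 and CDKN1C, both imprinted and both on chromosome 11, were among the largest changes in W308R. Of the 32 other imprinted genes measured, 1 was called with a change over 2-fold (3.12%, against 4.74% of other genes), an odds ratio of 0.648 with a 95% interval from 0.0159 to 3.90. This decides neither for nor against a wider change of imprinted dosage, since the interval is wide. KCNQ1 (1.77), OSBPL5 (0.93) and SLC22A18 (0.43), on the same chromosome, were also called higher, and were picked out after their values were seen.

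Other splits of the libraries were compared with the real groups. For each pair of genotypes there are 10 splits of the 6 libraries, too few for a share under 0.05. In edgeR fits of those libraries, the real split called 3159 genes for E690K against WT, 5200 for W308R against WT and 2489 for W308R against E690K. The highest other split called 0 in each, so that 1 of the 10 splits called as many. At an unadjusted p under 0.05 (edgeR), the real splits had 5691, 6902 and 5079 genes and the highest other splits 614, 738 and 1995. The value of 1995 belongs to the split that sets E690K libraries 1 and 2 with W308R library 1, the libraries with negative GC trends, against the others; with that side as a term, 4633 genes were called between the mutants. For lists, the real splits called 18, 16 and 12 and the highest other splits 17, 13 and 12, with 1, 1 and 3 of the 10 splits as high. Camera at a preset correlation thus called many lists in mixed groups of these libraries too. The sides of such a split still hold unequal numbers of libraries per genotype, so part of the genotype difference remains. These splits therefore cannot show how many lists camera calls by chance, nor rank list calls against gene calls. The list calls still depend on the preset correlation, as 0, 2 and 0 were made with an estimated one in all libraries. For the joint test, 1 of 80 drawn splits of the 9 libraries, the real one, called 5906 genes, and the highest other called 933. Random assignment of the libraries to groups therefore does not account for the 5906 calls. Each genotype is 1 clone, so differences between clones or their preparations are not excluded. For the genes shared by both mutants, 1 of 80 splits, the real one, gave 1253 and the highest other 617. Most splits that mix genotypes call no genes at all and so have none to share. This count therefore cannot decide whether the mutants share change beyond their common WT libraries. In the split with 933 genes, all 3 E690K libraries stayed together.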
